A study of Mus musculus with 4 samples.

How the data were processed

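RNA levels were measured in whole fetal brain of C57BL/6J mice on 2-colour Agilent arrays with probes of 60 bases. Per the series design text, dams were deprived of food overnight on gestation day 17 (food deprivation, FD), or received 50% of the chow eaten by controls from gestation day 10 to 17 (food restriction, FR), and fetuses were taken by caesarean section on gestation day 18; the text names that day for FR and leaves it implicit for FD. RNA of 5 fetuses was pooled per group, per the labels, and each treated pool was hybridised with a control pool on 2 arrays with the dyes exchanged. The series holds 4 arrays, all from 1 slide. Array 1 of each comparison carried the treated pool in Cy5 and array 2 carried it in Cy3. Whether FD and FR used one control pool is not stated.

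The deposited scanner files hold, per the file headers, the mean pixel intensity of each spot and the median intensity of its local background in the green and red channels, both uncorrected, from Agilent Feature Extraction 9.5.3.1. The same files hold a log10 ratio of red over green that the scanner software had background-subtracted, spatially detrended and dye-normalised before the authors deposited it, per the file headers. They also hold flags of 0 or 1 per spot for signal well above background, saturation and outlier pixels, per the file headers. The deposited value table carries no stated unit. Set against the scanner ratio, converted from log10 to log2, on spots well above background, its 4 columns correlated with it at r = 1, -1, 1 and -1, with slopes of the same values and differences up to 5.5e-06, so the authors' values are log2 ratios of treated over control without further centring. Over all spots, dim ones included, the same r was 0.840, -0.872, 0.927 and -0.887, and how the authors made the values of dim spots is unknown. The column medians were -0.03, 0.03, -0.03 and 0.01.

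The intensities were corrected with normexp (offset 50) and normalised with loess within each array in limma 3.58.1 under R 4.3.3. Control spots had weight 0 in the loess and were then left out, as were spots with an outlier flag in either channel. Array 2 of FR carried a bright patch whose local background reached 65319, and the normexp fit on all of its spots failed to resolve the dim signals. Spots with a local background over 2 times the array median, 3 on array 1 of FD, 44 on array 2 of FR and 0 on both others, were therefore left out before normexp. That exclusion was chosen after the values were seen; the plan as first written was the fit on all spots, which is kept among the alternatives. Spots of one probe were averaged, and the sign of the swapped arrays was turned so that every value is log2(treated/control).

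A probe counted as measured in a comparison when it was well above background in both channels on both arrays, and the brightest measured probe stood for its gene. Of 41174 probes, 26918 were named through their sequence identifier in the mouse reference table (assembly GRCm38.p6, used for names only), 5082 through a current symbol and 817 through an older symbol, and 8357 kept the file's name. Coordinates are those of the array files on build mm9, which give no exon or untranslated region.

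Each condition is 1 pool and both arrays of a comparison hold the same pair of pools, so the biological replication is n = 1 and no test or p-value was computed. Before the data were examined, the comparisons, the alternatives, the gene and marker lists and the following rules were fixed. A gene passed when it was at least 1.5-fold higher, or at least 1.5-fold lower, in the treated pool on both arrays. For FD against FR, the log2 ratios of arrays with equal dye orientation were subtracted and the same size was required in both differences. Genes passing in both comparisons were set beside the number that independent lists would share and beside 100 simulations of unchanged pools against one shared control. A gene not well above background in one pool and well above it in the other on both arrays got a lower bound on its fold, from channel signals after loess and Aquantile. For each list, the median log2 ratio of its measured genes was placed among 10000 random lists of equal size matched in 20 intensity bins, and a list stood apart at or below percentile 2.5 or at or above 97.5. Percentiles describe these pools and are not p-values. Lists with under 5 measured genes got values only. Of the 20 gene lists and 20 marker lists fixed, the sex-linked list was too small for a percentile.

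The named genes are the 12 highest and 12 lowest passing genes of each comparison with control and the 6 highest and 6 lowest of FD against FR, names that are not gene symbols left out. Up to 6 genes per direction are named for the overlap, up to 3 for detection in one pool, and up to 4 per list by absolute change whether or not they passed. Some genes that these rules take are left unnamed. Lists of skeletal muscle, brown fat, bone, liver and plasma protein, neutrophil and pituitary hormone genes (6 lists) were added after the named genes had been seen. They overlap the fixed marker lists and hold genes picked because they led the comparisons, so they are not independent evidence. The chaperone list was split into endoplasmic reticulum members and cytosolic or mitochondrial members after its median had been seen.

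The steps were tested on simulated arrays built from the real intensities with technical noise and dye bias only. For FD, with 17951 genes run, 74% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold passed, with median estimated folds of 1.74 and 3.27. For FR, with 18550 genes run, the shares were 75% and 98%, with median estimated folds of 1.77 and 3.31. Of the genes left unchanged, 0 of 17726 in FD and 0 of 18325 in FR passed, which leaves out variation between pools. The simulations of unchanged pools against one shared control, whose gene variation was drawn from the FD log2 ratios, had 31.7 genes passing for FD and 32.5 for FR. A list shifted on purpose fell at percentile 0 in both, and an unshifted list at 34.9 in FD and 24.3 in FR.

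Alternatives were no background correction, normexp with offset 0, the scanner's processed log ratio, median centring in place of loess, the deposited value table, a filter on dim probes in one condition or none, other size rules (2-fold, 0.75-fold for lower genes, the mean of both arrays), the mean over all probes of a gene, and each array alone. The added ones were normexp on all spots and counts without the genes of the 6 added lists. Array slide and scan were not run as a block because the series has 1 slide and 1 scan. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.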

Results

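Expression was measured in RNA pools of fetal mouse brain, each made from 5 fetuses: brains of fetuses whose dams were deprived of food overnight (FD), brains of fetuses whose dams had 50% of normal chow over the second part of pregnancy (FR), and the control RNA hybridised with each. The control RNA of the FD arrays and that of the FR arrays are called control pools here, although the labels do not say whether they were separate. Every comparison has 1 pool per condition and 2 arrays with exchanged dyes, so only technical error can be estimated and no difference was tested. Variation between pools cannot be told apart from an effect of the treatment. Each array held 43379 spots other than controls. In the treated channel, 79.1% and 73.5% of them were well above background on FD arrays 1 and 2, and 84.2% and 75.6% on FR arrays 1 and 2. In the control channel the shares were 71.4% and 81.0% for FD and 75.6% and 85.3% for FR. The technical SD of the mean log2 ratio of a dye swap was 0.0718, which leaves out variation between pools. The single pool per condition and the number of arrays limit every value below. The series title places the study in the field of developmental origins of health and disease, and the comparisons ask which transcripts of the fetal brain differ after a short and after a long shortage of maternal food.

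After overnight food deprivation, many skeletal muscle genes, a few brown fat genes and the pituitary hormone genes Gh and Pomc were lower in the FD pool than in its control pool. The fast muscle myosin light chain Myl1 was 7.60-fold lower, troponin C of fast muscle (Tnnc2) 5.91-fold lower and its troponin I partner Tnni2 4.68-fold lower. Fabp4, the fatty acid binding protein of fat cells, was 8.48-fold lower, and Ucp1, the uncoupling protein of brown fat, was 2.88-fold lower. Growth hormone (Gh) was 2.87-fold lower and Pomc, the precursor of corticotropin and melanocortins, 2.07-fold lower. For both, the control pool of the FD arrays stood above all other pools. Its log2 channel signal of Gh was 7.93, against 6.41 in FD, 5.99 in FR and 6.18 in the control of FR. For Pomc the signals were 9.95, against 8.90, 8.83 and 8.86. Among higher genes, Soga1 was 2.00-fold higher, the plasma protein gene Ahsg 1.83-fold, the cold-inducible RNA-binding protein Rbm3 1.70-fold, the metal-binding Mt2 1.63-fold and the transferrin receptor Tfrc 1.57-fold.

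Of 17951 genes measured on the FD arrays, 17 passed the size rule as higher and 22 as lower, and 6 of these 39 have no gene symbol. The probe of Fabp4 (A_51_P336833) lies on chromosome 3 from 10204452 to 10204511, that of Myl1 (A_51_P416858) on chromosome 1 from 66970948 to 66971007, and that of Pomc (A_52_P671543) on chromosome 12 from 3960413 to 3960472 (build mm9). The log2 ratios on arrays 1 and 2 were -3.22 and -2.95 for Fabp4, -3.08 and -2.77 for Myl1, -2.65 and -2.48 for Tnnc2 and -0.95 and -1.14 for Pomc. Mean log2 ratios were -2.14 for the myosin light chain Mylpf, -1.87 for Sln, a regulator of the muscle calcium pump, -1.69 for skeletal actin Acta1, and -1.58 and -1.46 for the embryonic and perinatal myosin heavy chains Myh3 and Myh8. In FR the same 12 lower genes lay between -0.20 (Myh8) and 0.15 (Myh3). The other higher genes were Mrpl15 at 0.99, Erdr1 at 0.84, the ribosomal protein gene Rps6 at 0.77, Zfp672 at 0.65, Serpina1d at 0.65, Igfbp1 at 0.62 and Tmem269 at 0.61. Another measured probe existed for 6 of the 24 named genes. It kept the sign for Soga1 (0.23), Fabp4 (-2.73) and Myh3 (-1.22), and had the opposite sign for Rbm3 (-0.18, from a probe near background). For Zfp672 it had no clear direction (mean 0.04, with 0.14 and -0.06 on arrays 1 and 2). For Mrpl15 the mean had the opposite sign (-0.04). Both of these means were smaller than the technical SD of 0.0718.

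**Figure D1:**
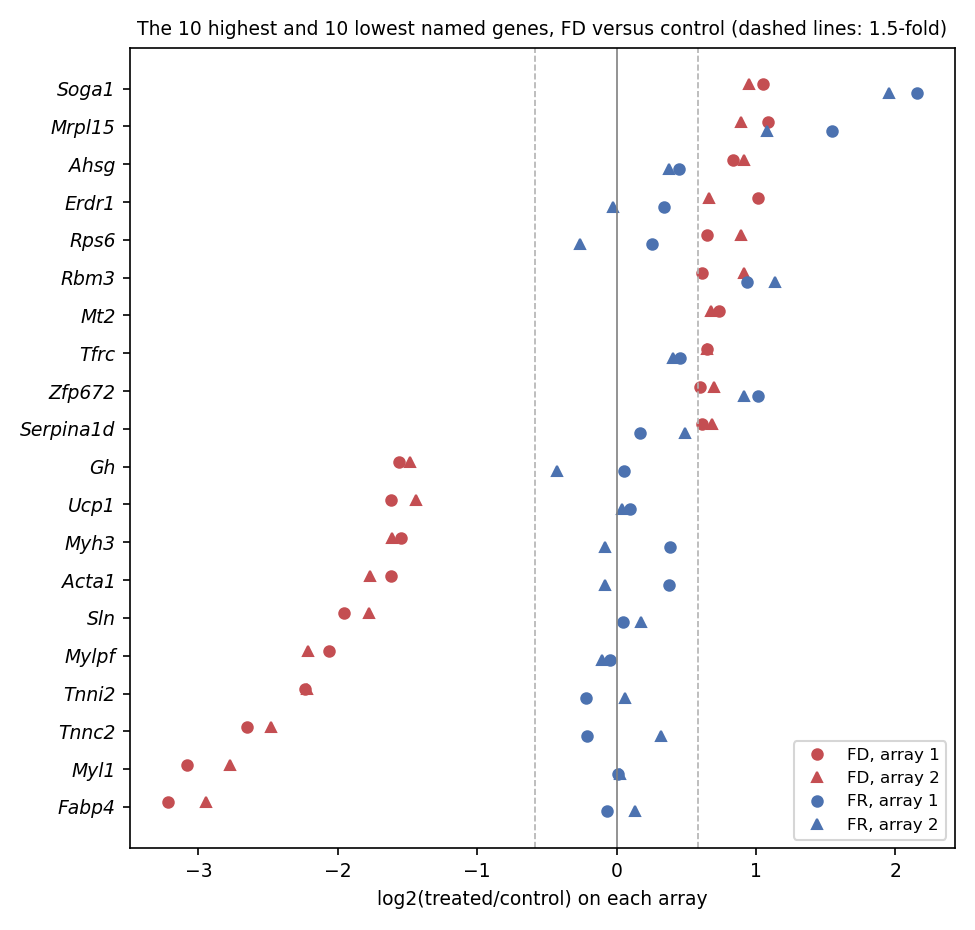
Log2 ratio of treated over control on each array (horizontal axis) for the 10 highest and 10 lowest genes named in FD versus control, with FD in red, FR in blue, array 1 as circles and array 2 as triangles; dashed lines mark 1.5-fold. Fabp4 and Myl1 lie at -3.08 and -2.93 in FD as means of both arrays, while both lie at 0.03 and 0.02 in FR. Rps6 is drawn from different probes in FD and FR, and on the probe drawn for FD its mean in FR is 1.47.

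Marker genes of muscle, cartilage and bone, a list fixed in advance for tissue next to the brain, had 9 of 17 measured members lower in FD and 0 higher. The list median was -0.85 (percentile 0 of the random lists), with Myl1, Tnnc2, Tnni2 and Mylpf leading. Of 40 measured genes of the skeletal muscle list added later, 12 were lower and the median was -0.31. In channel levels, the mean log2 signal of 39 muscle genes was 7.85 in the control pool of the FD arrays, 7.20 in the FD pool, 7.34 in the FR pool and 7.30 in the control pool of the FR arrays. The brown fat list, also added later, had 3 of 11 members lower (Fabp4, Ucp1 and Car3 at -0.98) and a median of -0.11 (percentile 0.07; -0.14 and -0.20 on arrays 1 and 2), with levels of 8.25 in the control pool of the FD arrays, 7.62 in FD, 7.56 in FR and 7.68 in the control of FR. The added bone list had 2 of 12 members lower, Spp1 at -0.96 and Col1a1 at -0.82, with a median of -0.16 (-0.12 and -0.27 on arrays 1 and 2). Pituitary markers had 2 of 8 members lower, Gh and Pomc, with a median of -0.06 (percentile 4.52; 0.01 and -0.19 on arrays 1 and 2). The added pituitary hormone list had a median of -0.29 over 5 genes, with Cga at -0.29 and Lhb at -0.05 (0.14 and -0.25 on arrays 1 and 2), and levels of 7.93 in the control pool of the FD arrays, 7.35 in FD, 7.32 in FR and 7.33 in the control of FR.

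**Figure D2:**
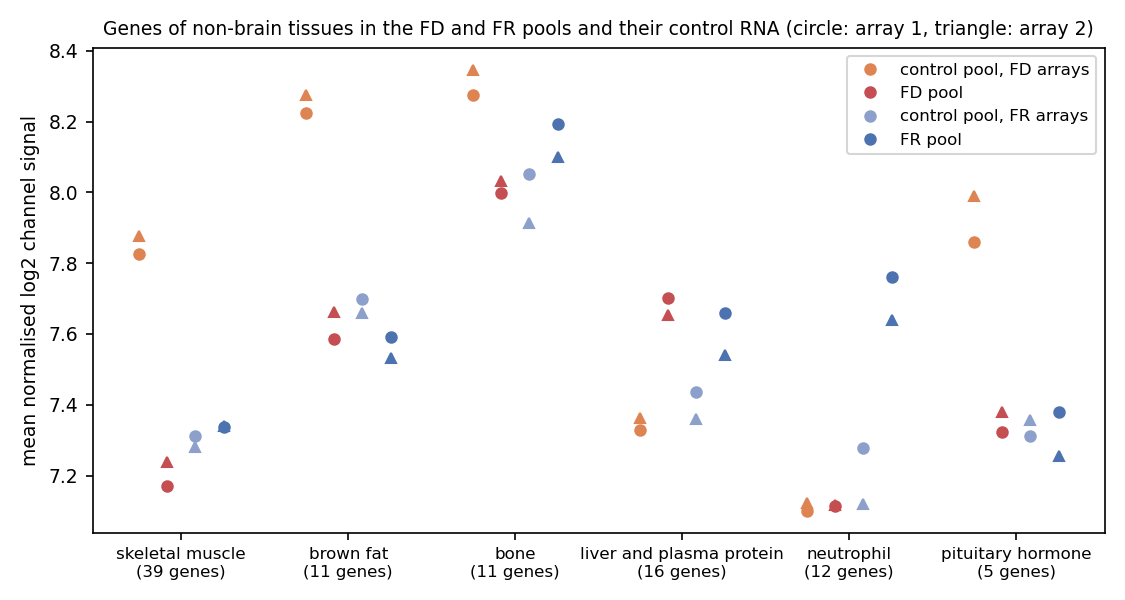
Mean log2 channel signal (vertical axis) of the 6 added lists of non-brain tissues in the FD and FR pools and the control RNA of each, with array 1 as circles and array 2 as triangles; the number of genes stands under each list. The control pool of the FD arrays lies highest for skeletal muscle (7.85), brown fat (8.25) and pituitary hormones (7.93), and the FR pool lies highest for neutrophil genes (7.70).

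Genes of cholesterol synthesis were lower as a group in FD. Of 23 measured members 18 were negative on both arrays, the median was -0.22 (percentile 0), and 0 passed the size rule. Hsd17b7 was at -0.61, the sterol carrier Stard4 at -0.47, and the pathway enzyme Mvd at -0.40. Heat shock and endoplasmic reticulum chaperone genes had a median of -0.22 over 28 members (percentile 0), 18 of them negative on both arrays and 0 passing, with Sdf2l1 at -0.58, Calr and Hsp90b1 at -0.44 and Hsph1 at -0.38 (-0.15 and -0.61 on arrays 1 and 2). Fatty acid synthesis genes had a median of -0.08 (percentile 1.89; Acly -0.41, Scd1 -0.40), and cell cycle genes had a median of -0.08 over 30 members (percentile 0.06; Top2a -0.25, Mki67 -0.19). On arrays 1 and 2 alone, these medians were -0.04 and -0.18 for fatty acid synthesis and -0.03 and -0.12 for the cell cycle. The genes gave -0.11 and -0.69 (Scd1), -0.39 and -0.12 (Top2a) and -0.26 and -0.12 (Mki67). Markers of neural progenitors had a median of -0.11 (percentile 0.93), led by Nes at -0.24 and Eomes at -0.23 (-0.12 and -0.33 on arrays 1 and 2). Neuron markers had a median of -0.10 (percentile 1.75) and synaptic genes of -0.05 (percentile 0.89; -0.08 and -0.04 on arrays 1 and 2), and the signs of both turned under median centring, to 0.03 and 0.01.

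Higher as groups in FD were circadian clock genes (median 0.08, percentile 99.3, Nr1d2 at 0.37) and amino acid and integrated stress response genes (median 0.07, percentile 99.0, Sesn2 at 0.39 and Trib3 at 0.25), with 0 members passing in either. Markers of retina and lens had a median of 0.09 (percentile 99.9, Cryaa 0.24), those of hindbrain and spinal cord of 0.08 (percentile 98.5, Hoxb3 0.39, Hoxa5 0.37), and those of microglia and macrophages of 0.08 (percentile 97.7, Tyrobp 0.27, C1qb 0.24). On arrays 1 and 2 alone, the median was 0.01 and 0.07 for the stress response genes, 0.09 and 0.04 for retina and lens, and 0.05 and 0.03 for microglia and macrophages. Single genes of these lists differed between the arrays too, with 0.53 and 0.21 for Nr1d2, 0.58 and 0.20 for Hoxb3, 0.62 and 0.12 for Hoxa5, 0.46 and 0.08 for Tyrobp and 0.15 and 0.32 for C1qb. Respiratory chain genes had a median of 0.07 over 26 members and ribosomal protein genes of 0.06 over 51, but array 2 alone gave -0.01 and -0.16. The glucocorticoid-responsive list had a median of 0.04 (percentile 80.8; 0.04 and 0.14 on arrays 1 and 2), with Mt2 passing at 0.71 and its neighbour Mt1 at 0.60 (0.88 and 0.32 on arrays 1 and 2). The added liver and plasma protein list had a median of 0.18 over 17 genes, 3 of them higher (Ahsg, Serpina1d and Igfbp1), and albumin (Alb) at 0.68. Arrays 1 and 2 alone gave list medians of 0.28 and 0.20. Of 19 gene lists 4 stood apart as higher and 5 as lower, where 0.95 would among lists of randomly drawn genes. Of 20 marker lists 3 and 3 did, where 1 would. These numbers leave out that genes of one list can vary together between pools.

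Across genes, the log2 ratios of the FD arrays correlated at r = 0.140, genes not being independent replicates, and 9 genes passed 1.5-fold in opposite directions on the arrays. The count of 39 for FD versus control was 18 with median centring (3 higher, 15 lower), 140 with the scanner's own log ratio, 17 without the genes of the added lists, and 103 or 185 with array 2 or array 1 alone.

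After a week of food restriction, the FR pool had higher mRNA of cold-inducible RNA-binding proteins and of neutrophil genes, and lower medians of chaperone genes and of astrocyte and oligodendrocyte lineage markers, than its control pool. Cirbp and Rbm3, whose products bind RNA and are induced by cold, were 2.49-fold and 2.05-fold higher. S100a9, a calcium-binding protein abundant in neutrophils, was 2.07-fold higher, and the protease inhibitor Csta1 2.13-fold. The chaperone Hspa4 was 1.95-fold lower, and Olig1, a transcription factor of the oligodendrocyte lineage, lay at a log2 ratio of -0.73. Soga1 was 4.16-fold higher, the transcription factor Hbp1 2.63-fold, and Igfbp1, a binding protein of insulin-like growth factors, 1.70-fold.

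Of 18550 genes measured on the FR arrays, 105 passed as higher and 84 as lower, and 46 of these 189 have no gene symbol. The probe of Soga1 (A_52_P257919) lies on chromosome 2 from 156841606 to 156841665, that of Cirbp (A_51_P272106) on chromosome 10 from 79634274 to 79634333, and that of Hspa4 (A_51_P200477) on chromosome 11 from 53073347 to 53073406 (build mm9). On arrays 1 and 2, the log2 ratios were 2.16 and 1.95 for Soga1, 1.44 and 1.19 for Cirbp, 0.85 and 1.25 for S100a9 and -1.05 and -0.78 for Zgpat. The other higher genes were Fam71e1 (mean 1.33), the mitochondrial ribosomal protein gene Mrpl15 (1.31), the microRNA host transcript Mir9-3hg (1.30), Armcx5 (1.15), the cytochrome c oxidase assembly factor Cox16 (1.13), Nosip (1.13) and the transcription factor Usf2 (1.06). Other lower genes were Rnf32 (-1.17), the mitochondrial ribosome recycling factor Mrrf (-1.13), the synaptic scaffold protein Lin7b (-1.09), the serine protease Prss56 (-1.06), Wdr78 (2.00-fold lower), the kinase Fn3k (-0.97), Zbtb40 (-0.96), the potassium channel Kcnj12 (-0.94), Zgpat (-0.92) and the diacylglycerol kinase Dgkk (-0.91). Of the 24 named genes, 10 have another measured probe, and 9 of those 11 probes had the same sign in the mean. The other probe changed sign between arrays 1 and 2 for Nosip (-0.15 and 0.17) and for Usf2 (-0.66 and 0.16). Cox16 (1.04), Rnf32 (-0.96), Mrrf (-0.78) and Soga1 (0.79) passed 1.5-fold there too in the mean, whereas Mrpl15 (-0.31) and Usf2 (-0.25) had the opposite sign, Nosip lay at 0.01, Prss56 at -0.41, Zbtb40 at -0.08, and Hspa4 at -0.10 and -0.07.

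**Figure D3:**
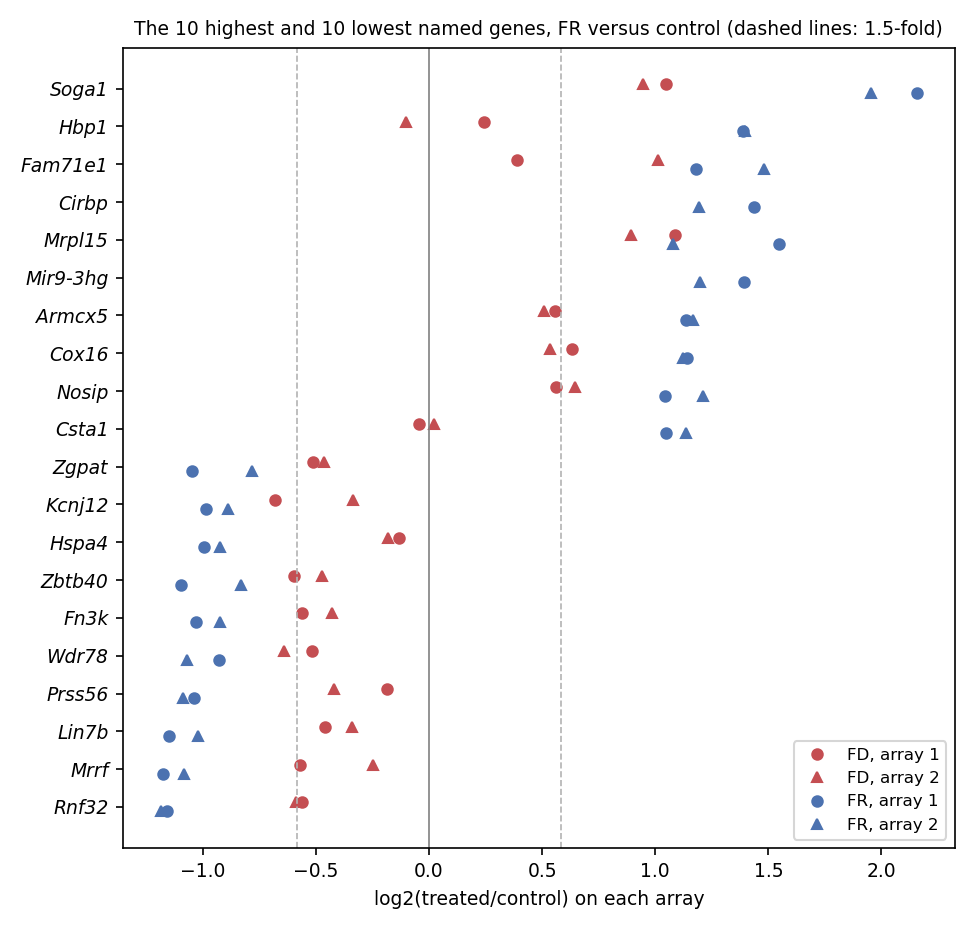
Log2 ratio of treated over control on each array (horizontal axis) for the 10 highest and 10 lowest genes named in FR versus control, with FD in red, FR in blue, array 1 as circles and array 2 as triangles; dashed lines mark 1.5-fold. Soga1 has the highest mean in FR (2.06) and Rnf32 the lowest of the named genes (-1.17), and Csta1 lies at -0.01 in FD. Hbp1 is drawn from different probes in FD and FR, and on the probe measured on all arrays FD minus FR is -0.79.

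Heat shock and endoplasmic reticulum chaperone genes had 3 of 22 measured members lower in FR (Hspa4, Sdf2l1 at -0.76 and Pdia4 at -0.60), 14 negative on both arrays, a median of -0.23 and percentile 0. Xbp1, a transcription factor of the unfolded protein response, was at -0.65 without passing. Cholesterol synthesis genes had a median of -0.23 over 22 members (percentile 0.02), 15 negative on both arrays and 0 passing, single-array medians of -0.14 and -0.18, and Ebp at -0.56, Mvd at -0.47, Cyp51 at -0.41 (-0.11 and -0.71 on arrays 1 and 2) and Lss at -0.38. Synaptic genes had a median of -0.11 (percentile 0.09) and 17 of 33 members negative on both arrays. The GABA receptor subunit Gabra2 was at -0.67, the scaffold protein Shank3 at -0.50, and Nlgn3 and Sv2b at -0.46. Inflammation and complement genes had a median of -0.06 (percentile 0.86), single-array medians of -0.04 and -0.06, and the interferon-induced Isg15 at -0.59.

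Oligodendrocyte lineage markers had a median of -0.23 over 11 members (percentile 0.2), with Olig1 passing as lower, Gpr17 at -0.55 and Cnp at -0.49. Astrocyte markers had a median of -0.24 over 10 members (percentile 0.1), single-array medians of -0.15 and -0.29, and 0 passing. S100b was at -0.50, the water channel Aqp4 at -0.47 and Gja1 at -0.33 (-0.19 and -0.46 on arrays 1 and 2), while Aldoc went the other way at 0.44. On the probe of Aldoc measured on all arrays, FD lay above FR by 0.35. The probes chosen for Aldoc in each comparison would put FD below FR, so its direction may depend on the probe. Microglia and macrophage markers did not stand apart, with a median of -0.04 (percentile 20.6) and 0 of 13 passing. Muscle, cartilage and bone markers had a median of 0.08 (percentile 98.3) with 1 of 19 members passing, the cartilage collagen Col2a1 at 0.62. The neutrophil list, added after S100a9 and Csta1 had been seen, had 4 of 12 members higher and a median of 0.46, with Cstdc5 at 0.97 and Stfa1 at 0.92. Its mean level was 7.70 in the FR pool, 7.20 in the control of FR, and 7.11 in both pools of the FD arrays. The added liver and plasma protein list had 2 of 17 members higher, Igfbp1 at 0.77 and Afp at 0.72, with a median of 0.10 (0.16 and 0.13 on single arrays), and the added bone list had a median of 0.10 (0.15 and 0.17) with 0 of 13 passing. Single members that passed in lists near the middle were the ketone body enzyme gene Oxct1 at -0.69 and the complex I gene Ndufb2 at -0.91. Of 19 gene lists 0 stood apart as higher and 4 as lower (0.95 for lists of randomly drawn genes). Of 20 marker lists 1 and 2 did (1 for such lists).

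**Figure D4:**
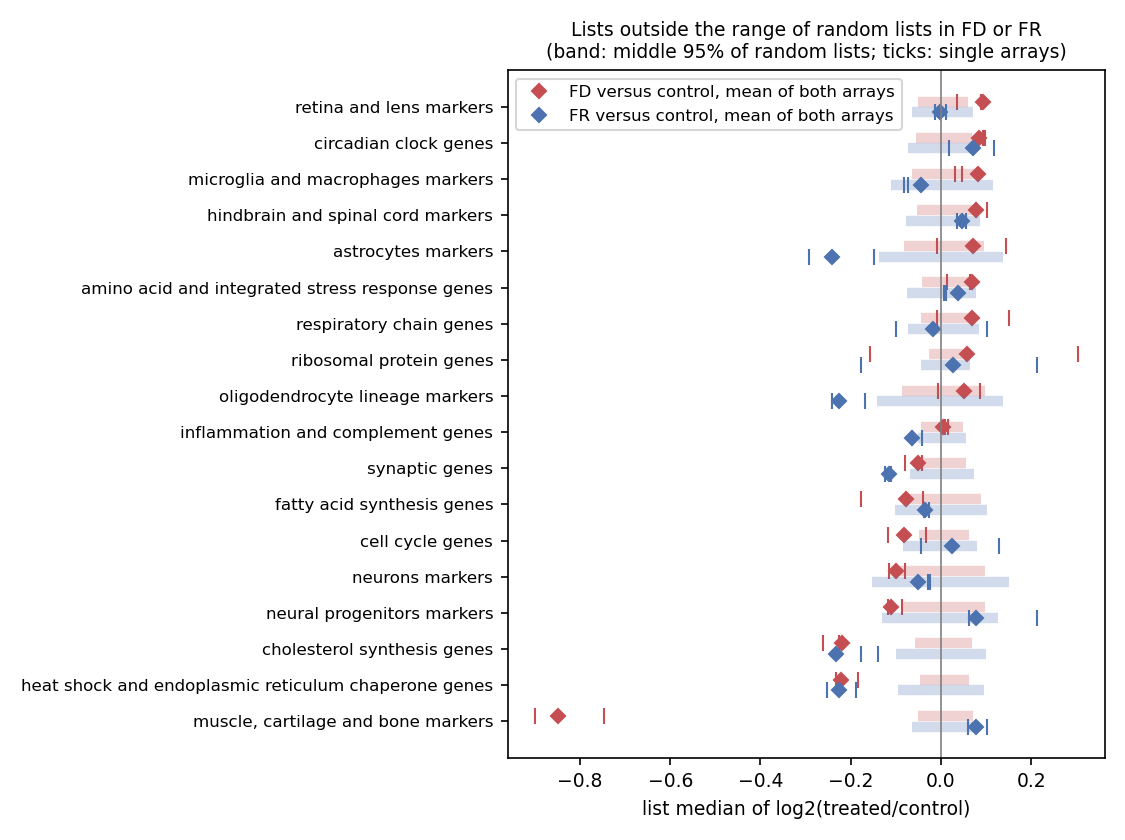
Median log2 ratio of treated over control (horizontal axis) for the fixed lists that stood apart in FD (red) or FR (blue); diamonds are means of both arrays, ticks single arrays, and bands hold the middle of the random lists. Cholesterol synthesis genes lie at -0.22 and -0.23 and chaperone genes at -0.22 and -0.23, while muscle, cartilage and bone markers lie at -0.85 in FD and 0.08 in FR; neuron markers and synaptic genes in FD turn sign under median centring, and respiratory chain and ribosomal protein genes in FD turn sign without replicate 1.

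Across genes, the FR arrays correlated at r = 0.422, and 1 gene passed 1.5-fold in opposite directions. The count of 189 for FR versus control was 30 with median centring (23 higher, 7 lower), 605 with the scanner's own log ratio, 14 with normexp fitted on all spots including the bright patch, and 488 or 561 with array 2 or array 1 alone.

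Set against each other, the log2 ratios to control were lower in FD than in FR for muscle, bone and neutrophil genes and higher for glial markers. Fabp4 differed by a log2 of -3.11, Myl1 by -2.94, Tnnc2 by -2.62, Tnni2 by -2.15, Mylpf by -2.06 and Sln by -1.98. For Fabp4 and the muscle list, most of the difference lay between the control pools. Fabp4 was at 6.85 in FD and 7.16 in FR, against 9.93 and 7.13 in their control pools. The mean level of the muscle list differed by -0.136 between FD and FR, and by 0.554 between their control pools. Above FR lay the interferon-induced Rtp4 (0.83), Hspa4 (0.80), Xlr4b (0.78), Prss56 (0.76), Ly6c2 (0.75) and Mrrf (0.72). Hspa4 was at -0.16 in FD and -0.96 in FR. Of 16750 genes measured on all arrays, 13 passed as higher in FD relative to FR and 46 as lower, and the pairs of equal dye orientation correlated at r = 0.485 across genes.

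Astrocyte markers had a median difference of 0.35 (percentile 100), with 8 of 9 members positive in both pairs, and S100b and Agt at 0.58. Oligodendrocyte lineage markers differed by 0.24 (percentile 99.95; Gpr17 0.54, Cnp 0.41) and microglia and macrophage markers by 0.14 (percentile 99.5; C1qc 0.26). Synaptic genes differed by 0.11 (percentile 99.9; Sv2b 0.48, Shank3 0.45, but Sv2a -0.36). Of their 32 measured members, 14 were positive and 7 negative in both pairs. Inflammation and complement genes differed by 0.07 (Isg15 0.52), appetite peptide genes by 0.07 with Pomc at -1.02, fatty acid oxidation genes by 0.08 (Oxct1 0.43) and ribosomal protein genes by 0.06, all at percentiles between 97.7 and 98.4. Below FR lay neural progenitor markers (-0.16, percentile 0.42; Notch1 -0.41, Neurog2 -0.40), cholesterol synthesis genes (-0.10, percentile 0.47; Fdps -0.35), circadian clock genes (-0.09, percentile 0.83; Csnk1e -0.41), DNA methylation and histone modification genes (-0.07, percentile 1.41; Suz12 -0.37), and thalamus and midbrain markers (-0.08, percentile 2.32; Lhx9 -0.29). Muscle, cartilage and bone markers had a median difference of -0.99 with 11 of 17 members passing, pituitary markers of -0.18 (percentile 0) with Gh at -1.33, and the added neutrophil list of -0.43 with 4 of 12 members passing as lower. In the separate pairs of arrays, the difference was -0.07 and -0.04 for cholesterol synthesis genes, 0.09 and 0.04 for ribosomal protein genes, 0.07 and 0.09 for synaptic genes, -0.05 and -0.28 for pituitary markers, and -0.11 and -0.01 for thalamus and midbrain markers. Notch1 had -0.66 and -0.15, and Lhx9 had -0.52 and -0.07. The added brown fat list had 3 of 11 members passing as lower, among them Ucp1 at -1.59 and Car3 at -1.11, and a median difference of -0.04 (percentile 19.7), which was -0.15 in one pair of arrays and 0.00 in the other. The difference holds both control pools as well as both treated pools, and the muscle level of the control pools differed (7.85 and 7.30). The count of 59 for FD against FR was 33 without the genes of the added lists, 28 (2 higher, 26 lower) with normexp fitted on all spots, and 259 (135 higher, 124 lower) with the scanner's own log ratio. It was 124 or 187 with one pair of arrays alone, and with median centring the split of higher and lower was 36 and 29.

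Genes higher in both treated pools included Soga1, the RNA-binding protein gene Rbm3 and Igfbp1. With each gene's brightest probe chosen again among those measured on all arrays, 17 genes were higher in FD and 107 in FR, and 12 were higher in both, where independent lists would share 0.109. Named among these 12 are Soga1 (log2 1.00 in FD and 2.06 in FR), Mrpl15 (0.99 and 1.31), Rps6 (0.77 and 1.47 on the probe measured on all arrays), Rbm3 (0.76 and 1.04), Zfp672 (0.65 and 0.96) and Igfbp1 (0.62 and 0.77). On the brightest probe of the FR arrays, Rps6 lay at 0.00. Another probe of Mrpl15, of similar brightness, lay at -0.04 in FD and -0.31 in FR. One of Zfp672, also of similar brightness, lay at 0.04 in FD. A second probe of Soga1 lay at 0.23 in FD and 0.79 in FR, and a dim one of Rbm3 at -0.18 and -0.14. Of 23 genes lower in FD and 79 lower in FR, 0 were shared (0.108 for independent lists), and 0 genes passed in opposite directions. The overlap of FD and FR held 14 lower genes with the scanner's own log ratio, 8 with offset 0 and 11 under the 0.75-fold rule. Cirbp was usable on 1 of the FD arrays, where it was at 0.70.

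The log2 ratios of FD and FR correlated across 16750 genes at Pearson r = 0.576 and Spearman rho = 0.536, and genes are not independent replicates. Of 186 genes passing in FR, 182 had the same sign in FD, and of 40 passing in FD, 27 had the same sign in FR. Simulated pools against one shared control, whose genes varied as widely as the FD ratios, gave r = 0.379 and same-sign shares of 77.9% for genes passing in FR and 78.3% for genes passing in FD, against 97.8% and 67.5% observed. They also gave 31.7 passing genes for FD and 32.5 for FR with 12.0 passing the same way, at most 24; the observed 12 came from longer lists, 40 genes for FD and 186 for FR. The covariance was 0.0175, against 0.00810 simulated, a difference of 0.00940. The measured FR ratios varied more widely than the FD ratios (SD across genes 0.201 and 0.144). The simulations did not copy that spread, so no surplus over a shared control can be read from these values. Array pairs of equal dye orientation correlated at 0.595 and 0.620, and pairs of opposite orientation at 0.144 and 0.140. The overlap of FD and FR was 2 genes with normexp fitted on all spots, 3 with median centring, 72 with the scanner's own log ratio, 46 or 82 with one array of each alone, and 0 at 2-fold.

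In one pool of a comparison alone, 39 genes were detected in all, or 221 with the weaker detection flag in one-sided detection. Of 16 genes detected in the control pool of the FD arrays and not in the FD pool, 1 had a bound of at least 1.5-fold, Cfd, a protease secreted by fat cells, at least 1.72-fold lower in FD. The bounds of the others started at 1.02-fold, and the collagenase Mmp13 and the adipocyte hormone Adipoq were each at least 1.48-fold lower. In the FD pool alone, 6 genes were detected, with Hao1 at least 1.12-fold, Pilra at least 1.07-fold and Olfr1258 at least 1.03-fold higher. For FR, 12 genes were detected in the control alone, led by Gbp4 (at least 1.13-fold lower), the lens protein gene Mip and Abitram (each at least 1.09-fold lower), and 5 genes without a symbol in the FR pool alone.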

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

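The tests in this part were not among the rules fixed before the data were examined. For some, the prediction was written before the test was run. These covered muscle gene levels in the control pools, the repeat of control-channel differences between array pairs, and the share of other probes agreeing in sign. The muscle levels used the skeletal muscle list, which was added after the named genes had been seen. The tests of a fall in the FD brains, of more tissue in the control pool, of shared control RNA apart from the added lists, of dye bias and of temperature were chosen after the result was seen.

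Marker genes of muscle, cartilage and bone were lower in FD on both arrays (-0.90 and -0.75) and higher in FR on both (0.10 and 0.06), a median difference of -0.989 between FD and FR that was not tested. The added bone list went the same way, with -0.16 in FD, 0.10 in FR and a median difference of -0.306, also not tested.

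The first pattern was the low level of skeletal muscle genes in FD. Less non-brain tissue in the FD pool alone is argued against by the control pool of the FD arrays, which lay above the control pool of the FR arrays by 0.554 on the log2 scale, most of the 0.647 by which it lay above FD. A fall of muscle transcripts in the FD brains as the whole cause is argued against too, by the mean of the muscle list. There the FD pool lay below the FR pool by only -0.136 and below the control of FR by -0.0923. Its difference from its own control was -0.647. Leading genes lay further down in FD, with Myl1 at 7.77 against 8.35 in FR and 8.34 in the control of FR. In the same order, Tnnc2 was at 8.35 against 8.83 and 8.78, and Myh8 at 8.94 against 9.12 and 9.31. A smaller fall of such genes in FD stays open. More non-brain tissue in the control pool of the FD arrays had the values it needs, as a hypothesis: that pool lay 0.571 above the mean of the other pools in muscle genes and was also the highest of the pools in brown fat, bone (8.31) and pituitary hormone genes, with Tnnc2 at 10.9 against 8.35 to 8.83, Fabp4 at 9.93 against 6.85 to 7.16 and Pomc at 9.95 against 8.83 to 8.90, but not in every member, since Lhb was at 8.26 against 8.41 in FR, Postn at 9.91 against 9.95 in FD and Col1a1 at 12.3 as in FR. It was the lowest in liver and plasma protein genes (7.35 against 7.40 to 7.68) and level with FD in neutrophil genes (both 7.11), so the hypothesis does not cover every non-brain tissue. The labels describe dissection that kept other tissues out. A difference of Pomc in brain cells stays open for the control pool of the FD arrays. Pomc in the FD pool (8.90) was not below FR (8.83) or the control of FR (8.86). Nor was Gh, at 6.41 in FD against 5.99 in FR and 6.18 in the control of FR.

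The second pattern was the correlation of FD and FR log2 ratios across genes. One control pool for both comparisons is argued against by the same muscle genes. The control-channel differences between the array pairs repeated at r = 0.557 across dye orientations, against 0.680 for the treated channels. Part of both is common to the arrays, as channels of different RNA gave 0.354 and 0.392. With the common part taken off, the control channels repeated 28.4% of what the treated channels did over all genes. These r values therefore do not decide between one control pool and separate ones. Dye bias as the whole cause is argued against by r = 0.140 and 0.144 between arrays of opposite orientation, where it would give 0 or less. Control RNA shared apart from the added lists cannot be told apart from separate controls, because the control channels repeated 7.30% of what the treated channels did after the common part was taken off and 54.3% before. A response common to both shortages of food stays open beside it.

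The third pattern was Rbm3 higher together with lower chaperone genes in both comparisons, and Cirbp higher in FR and at 0.70 on the single FD array that measured it. Faulty probes were not excluded, since 75% of the other measured probes (3 of 4 in each comparison) had the same sign, the exception being a dim probe of Rbm3 at -0.18 and -0.14, and Cirbp has 1 probe. Some probes with the same sign had far smaller changes. Those of Hspa4 in FR lay at -0.10 and -0.07 against -0.96 on the chosen probe. A probe of Pdia6 in FD lay at -0.05 against -0.35. A lower temperature of the treated fetuses as the one cause was tested on the kind of chaperone, as cytosolic and mitochondrial heat shock genes would then lie lower than those of the endoplasmic reticulum. The endoplasmic reticulum genes lay lower by -0.163 in FD and by -0.0386 in FR. The rule asked for more than the technical SD of a dye-swap mean, 0.0718, in both comparisons, so the test does not decide. That SD belongs to a single gene and does not measure the spread of a difference of list medians. Fetuses were placed on ice-cold saline, per the labels, and neither its duration nor an effect of maternal diet itself was tested.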

How the results depend on the processing

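The counts without the added lists were chosen after the values were seen. So was the main setting's exclusion of bright-background spots, and normexp on all spots is the background correction as first planned. The other alternatives were fixed beforehand. Counts are genes passing the 1.5-fold rule. The main counts were 39 for FD versus control, 189 for FR versus control, 59 for FD against FR and 12 for the overlap of FD and FR. In the same order they were 90, 433, 161 and 39 with normexp offset 0, and 140, 605, 259 and 72 with the scanner's log ratio, and the deposited value table gave 140, 605, 259 and 72 as well. Median centring gave 18, 30, 65 and 3, the 2-fold rule 11, 24, 19 and 0, and the 0.75-fold rule for lower genes 65, 368, 116 and 23. The mean of both arrays moved FR versus control to 338 and the overlap to 19. With one array alone the ranges were 103 to 185, 488 to 561, 124 to 187 and 46 to 82, since 1 array replaces 2 in the rule. Normexp on all spots gave 14, 28 and 2 for the last 3 counts, through the bright patch on FR array 2. Without the added lists, FD versus control had 17 genes (14 higher, 3 lower), FR versus control 181 and FD against FR 33 (13 higher, 20 lower). The cause of the other shifts was not tested.

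The split of higher and lower genes moved with median centring from 17 and 22 to 3 and 15 for FD versus control, from 105 and 84 to 23 and 7 for FR versus control, and from 13 and 46 to 36 and 29 for FD against FR. For FD against FR it was 135 and 124 with the scanner's log ratio and 64 and 97 with offset 0. The overlap of FD and FR split as 58 and 14 with the scanner's log ratio, 31 and 8 with offset 0, 12 and 11 with the 0.75-fold rule, and 27 and 19 or 68 and 14 with one array alone. The correlation of FD and FR log2 ratios across genes was 0.576, between 0.526 and 0.620 under the other settings, and 0.142 with opposite dye orientations. One-sided detection gave 39 genes in all and 221 with the weaker detection flag.

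Of the lists that stood apart, 4 had an FD median that turned sign. Synaptic genes went to 0.00552 and neurons markers to 0.026 with median centring. Respiratory chain genes went to -0.0095 and ribosomal protein genes to -0.157 without replicate 1, against 0.151 and 0.303 without replicate 2. The cause was not tested. Of 330 values of lists that stood apart, 207 stayed within the technical spread and 119 moved beyond it with the same sign. Of 528 values of named genes, 377 stayed and 151 moved, and 0 turned sign. Of 660 values of the other lists, 493 stayed and 167 moved. Of the 660, 112 had the opposite sign to the main value, 37 of them with one array alone, and 47 of 60 of these list medians were affected. No paired analysis was possible because the replicate numbers name the dye orientation of technical repeats and no result comes from a test. That refers to pairs of biological replicates. For FD against FR, arrays were paired by dye orientation alone and their log2 ratios subtracted. At most 85.3% of spots were well above background in a channel, and genes too dim in both pools were given no fold.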

Other observations

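No hypothesis was tested in this part, and its values come from the fixed lists and, where named so, from the added ones. In the comparisons with control given below, the medians of the lists of energy, hormone and stress genes lay within the range of the random lists. Of the genes named, Igfbp1, Gh, Pomc and, in FR, Oxct1 passed the size rule in these comparisons. The others did not pass, and several differed between arrays: in FD, Txnip (0.13 and 0.56), Peg3 (-0.54 and -0.12), Cpt1a (0.45 and 0.07), Dnmt3a (-0.62 and -0.11) and Uhrf1 (-0.54 and -0.25), and in FR, Txnip (0.19 and 0.72), Crhr1 (-0.58 and -0.28), Insr (0.57 and 0.24) and Mt1 (0.65 and 0.23). FoxO and insulin signalling genes had medians of 0.00 in FD and -0.02 in FR, with Txnip, whose transcription follows glucose, at 0.35 and 0.45, the receptor Igf1r at -0.34 in FD and the insulin receptor Insr at 0.41 in FR. Insulin-like growth factor and thyroid hormone genes had medians of 0.00 in FD and 0.05 in FR, with Igfbp1 passing as higher in both, Gh passing as lower in FD, and Igfbp3 at 0.20 and 0.48. Fatty acid oxidation and ketone body genes had medians of 0.05 and -0.03, and their members went both ways. In FD, Oxct1 was at -0.26, the carnitine transferase Cpt1a at 0.26 and Ppargc1a at -0.25. In FR, Oxct1 passed as lower at -0.69, Bdh1 was at -0.30 and Pdk4 at 0.29. Hypoxia and glycolysis genes had medians of -0.02 and -0.05, with the collagen hydroxylase P4ha1 at -0.34 in FD and -0.55 in FR and Pdk1 at -0.54 in FR. Appetite and neuroendocrine peptide genes had medians of 0.00 and -0.04, with Pomc passing as lower in FD, Cartpt at 0.24 in FD, and Crhr1 at -0.43 in FR. Immediate early genes had medians of -0.02 and 0.00, with Nr4a1 at 0.46 and Btg2 at 0.38 in FR. Imprinted genes had medians of 0.00 and 0.01, with the paternally expressed Mest at -0.37 and Peg3 at -0.33 in FD. DNA methylation and histone modification genes had medians of -0.04 and 0.02, with the de novo methyltransferase Dnmt3a at -0.36 in FD and -0.52 in FR and Uhrf1 at -0.39 in FD. Glucocorticoid-responsive genes had a median of 0.07 in FR, with Mt1 at 0.44. In FR, amino acid and integrated stress response genes had a median of 0.04, with the amino acid transporter Slc7a3 at -0.64. Slc7a3 passed as higher in FD relative to FR, at 0.66.

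Markers of further brain regions and cell types also stayed within the range of the random lists in FD and in FR. Medians in FD and FR were -0.02 and 0.02 for glutamatergic cortical neurons, 0.04 and 0.08 for GABAergic neurons (Dlx1 at 0.32 in FR), and -0.01 and -0.09 for striatal neurons (Penk at -0.29 in FR, -0.39 and -0.18 on single arrays). They were 0.00 and 0.05 for thalamus and midbrain, 0.03 and 0.01 for hypothalamus, 0.05 and 0.03 for cerebellum (Calb1 at -0.40 in FR), 0.02 and 0.01 for choroid plexus (Clic6 at 0.39 in FR), and -0.05 and -0.01 for endothelial cells and pericytes (Kdr at -0.24 in FD). Meninges and fibroblasts had medians of 0.04 and -0.01 with Col1a1 passing as lower in FD at -0.82 and lying at 0.48 in FR. Skin and epithelium had 0.03 and -0.01. Erythroid cells had 0.06 and 0.11, with Tfrc passing as higher in FD and the haem synthesis enzyme Fech at 0.64 in FR. Of the sex-linked genes 3 were measured, with the Y-linked Ddx3y at 0.31 in FD (0.43 and 0.20 on arrays 1 and 2) and 0.50 in FR (0.68 and 0.33), Uty at 0.10 and -0.02, and Kdm5d at 0.03 and -0.09. In FR, the added skeletal muscle list had a median of 0.02 with Cacng1 passing as higher at 0.97, the added brown fat list 0.03 with Cidea passing as lower at -0.68, and the added pituitary hormone list -0.03. The added neutrophil list had a median of 0.00 in FD.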
